A study of Mus musculus with 8 samples.

How the data were processed

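RNA from whole skin of newborn FVB mice of 4 genotypes was measured on 8 microarrays of 22690 probe sets, 2 arrays per genotype, each with a pool of RNA from 3 animals per the labels. RMA is the only tool that the submitters' processing notes name, with no version. The deposited values are standardized scores: tested on the file, all 22690 probe sets have mean 0 and SD 1 over the 8 arrays within 1e-06, and the values lie between −2.43 and 2.45. Whether logarithms were taken before this standardization is not given in the sources used here. The scores hold no expression level, so no filter on dim genes and no fold change could be computed, and a gene with a small absolute change counts as much as one with a large change.

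Gene symbols came from the platform annotation, matched by Entrez number to the RefSeq table of assembly GRCm38.p6. Of the probe sets, 20393 had 1 symbol, 691 had several and 1606 had none; 20364 of those with 1 symbol matched and 0 symbols changed. Only probe sets with 1 symbol were used for genes. The planned rule took the probe set with the highest mean, which is undefined when all means are 0, so 1 probe set per gene was taken by suffix (_at before _a_at, _s_at and _x_at) and then by lowest identifier. This left 12394 genes, 4958 of them with more than 1 probe set. Over these genes the median r of the probe set used with the others was 0.212. In 2185 of them (44.1%) it had a negative r with at least 1 other probe set. This low agreement bears on each value of a single gene and of a list below. Trp53 was not analysed here.

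Differences were fitted with limma 3.58.1 in R 4.3.3 on all 8 arrays with 1 mean per group and 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes within a comparison. A gene was called at an adjusted p under 0.05. The design fixed before the data were examined named limma's moderated test on log2 expression. On standardized rows the variances of different genes are tied together by construction, the prior took 35.1 degrees of freedom, and that test called 0 genes in every comparison. The main test is therefore limma's test without moderation, which does not depend on the scale of a row. This choice was made after the moderated test had been seen to call 0 genes, so the counts of called genes are exploratory, and the moderated counts are given beside them. Both tests were tested on simulated data with 200 changed genes. For double_null against control, 49.3% of the genes changed by 10 within-group SD and 3% of those changed by 5 were called by the test without moderation, with 12 false calls, and none by the moderated test.

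The 32 gene lists were fixed before the data were examined. The list of replication-dependent histones had fewer than 5 measured genes and was not tested. The other lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and then with an estimated correlation, with which no list passed in any comparison. Camera moderates its gene statistics, so the lists were tested also on the ordinary statistic, as an alternative chosen after seeing the data. The lists that did not pass in any comparison were p53 target genes, spinous and granular differentiation, apoptosis machinery, DNA damage response and repair, epithelial to mesenchymal transition, sterol and lipid synthesis, circadian clock, and the markers of dermal fibroblasts, endothelium, nerve, blood, sebaceous gland and the sex chromosomes.

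Named genes followed a rule fixed beforehand: Rb1; the 10 largest differences in each direction among called genes with groups that do not overlap for comparisons against control, 5 for the others; and the 5 smallest p where fewer than 5 were called. List members are examples chosen by p. For double_null against control, 50.1% of genes had groups that do not overlap, where chance gives 33.3%. The alternatives were quantile normalization, a replicate block, every probe set, the mean of a gene's probe sets, array weights, only the groups compared, an additive model, 2 groups of 4 arrays and leaving out each array. The planned moderated test became an alternative after the data had been seen. Added then were setting each array's median to 0, a crossed replicate block, the count of control probe sets by array group and a simulation of the overlap that shared controls give. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.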

Results

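The data were 8 oligonucleotide microarrays of whole skin from newborn FVB mice, an inbred strain. The mice had lost pRb (gene Rb1), p53 (gene Trp53), both or neither in their stratified epithelia, and each array was hybridized with RNA pooled from 3 animals of 1 genotype. There were 4 groups of 2 arrays: control, pRb_null, p53_null and double_null. pRb holds back entry into S phase, and p53 drives cell cycle arrest and apoptosis after damage. The deposited value of each probe set was a standardized score, with mean 0 and SD 1 over the 8 arrays. All differences below are therefore in units of a gene's own SD over the arrays, and neither expression levels nor fold changes can be given. Because a score is bounded, a large difference marks a gene whose arrays separate cleanly and not a gene with a large fold change. The number of arrays limits the precision. The sources used here do not say whether the 2 arrays of a genotype held separate pools, so p-values measure the spread between these arrays, which may be technical. Across the 22690 probe sets, each array correlated best with the other array of its own genotype, with r across probe sets from 0.118 to 0.337, and the highest correlation with an array of another genotype was 0.093.

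Rb1 was measured by 1 probe set. Its scores were 1.20 and 0.80 in control, −0.71 and 0.44 in pRb_null, 0.50 and 0.22 in p53_null and −0.55 and −1.90 in double_null. The difference from control was −1.14 ± 0.65 (SE) in pRb_null, with an adjusted p of 0.67, and −2.23 ± 0.65 in double_null, with an adjusted p of 0.22. Neither passed the test. The position of this probe set relative to the deleted part of the gene is not given in the sources used here, and whole skin also holds cells outside the epithelium, so the probe set does not check the labels. Trp53 was not analysed here.

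**Figure D1:**
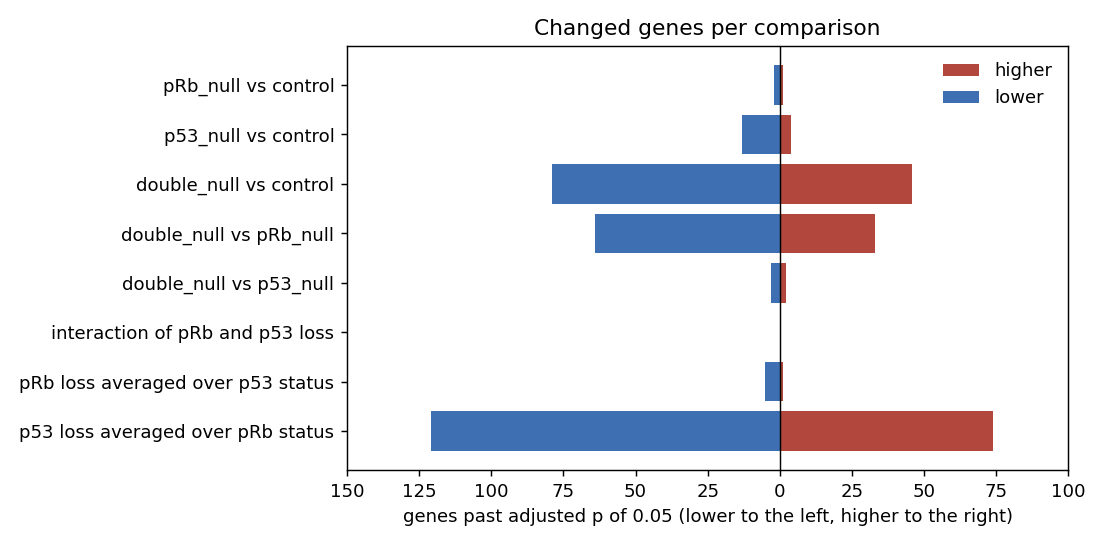
Number of genes past an adjusted p of 0.05 in each of the 8 comparisons (horizontal axis, genes; bars to the left are lower and bars to the right higher). The bars are longest for p53 loss averaged over pRb status, with 74 higher and 121 lower, and no gene passed for the interaction.

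The first comparison asked what loss of pRb alone does to newborn skin. Genes of E2F activity and DNA replication, the programme that pRb represses, were higher as a group in pRb_null than in control. The median difference of the 58 measured members was 1.02, with 9 members higher and 0 lower at an unadjusted p under 0.05, and 0 passing either over all genes or adjusted over the list alone. The list test gave an adjusted p of 9.1e-05, and adjusted p = 0.61 with an estimated correlation. Among the members, the replicative helicase subunit Mcm6 differed by 1.97 ± 0.27 (adjusted p = 0.24), the sliding clamp Pcna by 1.89 ± 0.40 (adjusted p = 0.36) and the primase Prim1 by 2.31 ± 0.50 (adjusted p = 0.37).

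Markers of skeletal muscle, a tissue under the skin, were also higher in pRb_null, with a median difference of 1.26 over 34 members and an adjusted p of 0.00029 (adjusted p = 0.61 with an estimated correlation). The members did not move as 1 block: 10 were higher and 4 lower adjusted over the list alone. Ckm, the muscle creatine kinase, differed by 2.62 ± 0.19 (adjusted p = 0.18), whereas the embryonic myosin Myh3 differed by −1.44 ± 0.17 (adjusted p = 0.20) and the slow troponin Tnnc1 fell by 1.43 ± 0.05 (adjusted p = 0.046). Adipocyte markers were higher, with a median of 0.89 over 17 members, 7 of them higher adjusted over the list alone, and an adjusted p of 0.035 (adjusted p = 0.70 with an estimated correlation). The hair follicle list had a median of −0.32 and an adjusted p of 0.30. Over all 12394 genes, 3 changed. Ptprf, a receptor tyrosine phosphatase, rose by 2.58 ± 0.09, and Ints6l fell by 1.79 ± 0.07 together with Tnnc1, each with an adjusted p of 0.046. Krtap16-3 (−0.66 ± 0.03) and Zcchc9 (−1.75 ± 0.08) had the next smallest p, with an adjusted p of 0.060 each. Of the other probe sets of Ptprf, 1 went the other way, at −0.53, and 1 agreed, at 2.34. The count of changed genes was 0 or 1 with any array left out, and quantile normalization and a replicate block each gave 0. Of the 64 control probe sets on the array, 20 scored lower in both control arrays than in every mutant array, 10 of them for mouse genes such as Gapdh and 10 bacterial, where chance gives 3.6%; over all probe sets the share was 7.0%. This difference runs with each comparison that uses the control arrays, the interaction and the averaged effects included. Over all 46 mouse and bacterial control probe sets, 18 were higher and 0 lower in pRb_null at an unadjusted p under 0.05, with a median of 1.47. The test behind these counts was limma's linear model without variance moderation, and limma's moderated test, which had been planned, called 0 genes in each of the 8 comparisons. At an unadjusted p under 0.05 there were 1159 genes in the first test and 1135 in the moderated test, where chance gives 620. With 1 array left out at a time, the E2F list lost its call without control replicate 1 (median 0.67). The muscle list lost its call without pRb_null replicate 2 (median 1.18). The adipocyte list lost its call without either control array, pRb_null replicate 2 or either p53_null array. Fits without a p53_null or double_null array leave the differences between pRb_null and control unchanged.

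The second comparison asked the same of p53 alone. Genes of the hair follicle and hair shaft keratins were lower in p53_null than in control. The median difference of the 39 measured members was −1.42. Of them, 2 fell over all genes, 31 adjusted over the list alone and 32 at an unadjusted p under 0.05. Not all members were lower: Shh differed by 2.03 ± 0.38 and Lhx2 by 2.03 ± 0.74. The list test gave an adjusted p of 3.6e-06 (adjusted p = 0.52 with an estimated correlation). Krtap15 fell by 2.06 ± 0.08 (adjusted p = 0.016) and Krtap14 by 2.12 ± 0.12 (adjusted p = 0.040). Both encode keratin-associated proteins of the hair shaft, a family of similar genes whose probes may cross-hybridize, so single members are uncertain. Members outside that family were also low: the shaft keratin Krt35 differed by −1.15 ± 0.10 (adjusted p = 0.084). Mast cell markers were higher, with a median of 1.87 over 10 members, 6 of them adjusted over the list alone, and an adjusted p of 0.00027 (adjusted p = 0.28 with an estimated correlation). The mast cell tryptase Tpsab1 differed by 2.38 ± 0.18 (adjusted p = 0.068) and the carboxypeptidase Cpa3 by 2.16 ± 0.20 (adjusted p = 0.089).

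The mitosis list was higher in p53_null, with a median of 0.33 over 58 members and an adjusted p of 0.00028 (adjusted p = 0.28 with an estimated correlation). Of its members, 4 were higher adjusted over the list alone, among them the kinesin Kif20a (2.46 ± 0.28, adjusted p = 0.10). The E2F list had a median of 0.43 and an adjusted p of 0.016 (adjusted p = 0.52 with an estimated correlation). Adipocyte markers were lower, with a median of −1.15, 9 lower and 1 higher adjusted over the list alone, and an adjusted p of 0.023 (adjusted p = 0.52 with an estimated correlation). The member that went up was Ucp1, the uncoupling protein of brown fat (1.32 ± 0.09, adjusted p = 0.060). The list of p53 target genes showed no shift that passed, with a median of −0.22 and an adjusted p of 0.87. Cdkn1a, the cell cycle inhibitor p21, differed by −2.45 ± 0.29 (adjusted p = 0.11) by the probe set used, while its other probe set differed by 0.24.

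In all, 17 genes changed in p53_null, 4 up and 13 down. Those that rose were Fscn1 (2.51 ± 0.09), an actin-bundling protein, Rxylt1 (1.85 ± 0.07), Ptprf (1.75 ± 0.09) and Tnnc1 (1.12 ± 0.05). Among those that fell were the hair shaft genes Krtap19-3, Krtap16-3, Krtap14, Krtap15 and Krtap19-9b, with differences from −2.19 to −2.01. Further genes that fell were Cap1 (−2.24 ± 0.10), Ints6l (−2.22 ± 0.07), the Wnt receptor Fzd6 (−2.05 ± 0.11), the connexin Gjb6 (−2.03 ± 0.10) and Slurp1 (−1.85 ± 0.07), a secreted protein of the epidermis. Of the other probe sets of Fscn1, 1 had the opposite sign (−0.58) and 2 agreed (1.57 and 1.66), and of those of Ptprf 1 had the opposite sign (−1.05) and 1 agreed (1.77). Leaving out any single array gave 0 to 7 changed genes, and quantile normalization and a replicate block each gave 0. Of the 46 control probe sets, 18 were higher and 2 lower in p53_null at an unadjusted p under 0.05, with a median of 1.20. The adipocyte and E2F lists lost their call without control replicate 1. The adipocyte list lost it also without p53_null replicate 2, and the E2F list without p53_null replicate 1. The E2F median was 0.03 without control replicate 1 and 0.88 without control replicate 2. The mitosis median was 0.73 without control replicate 2 and 0.54 and 0.51 without p53_null replicates 1 and 2. The Y-linked gene Eif2s3y scored lower in p53_null than in control, without passing the test (−1.86 ± 0.56, adjusted p = 0.31).

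**Figure D2:**
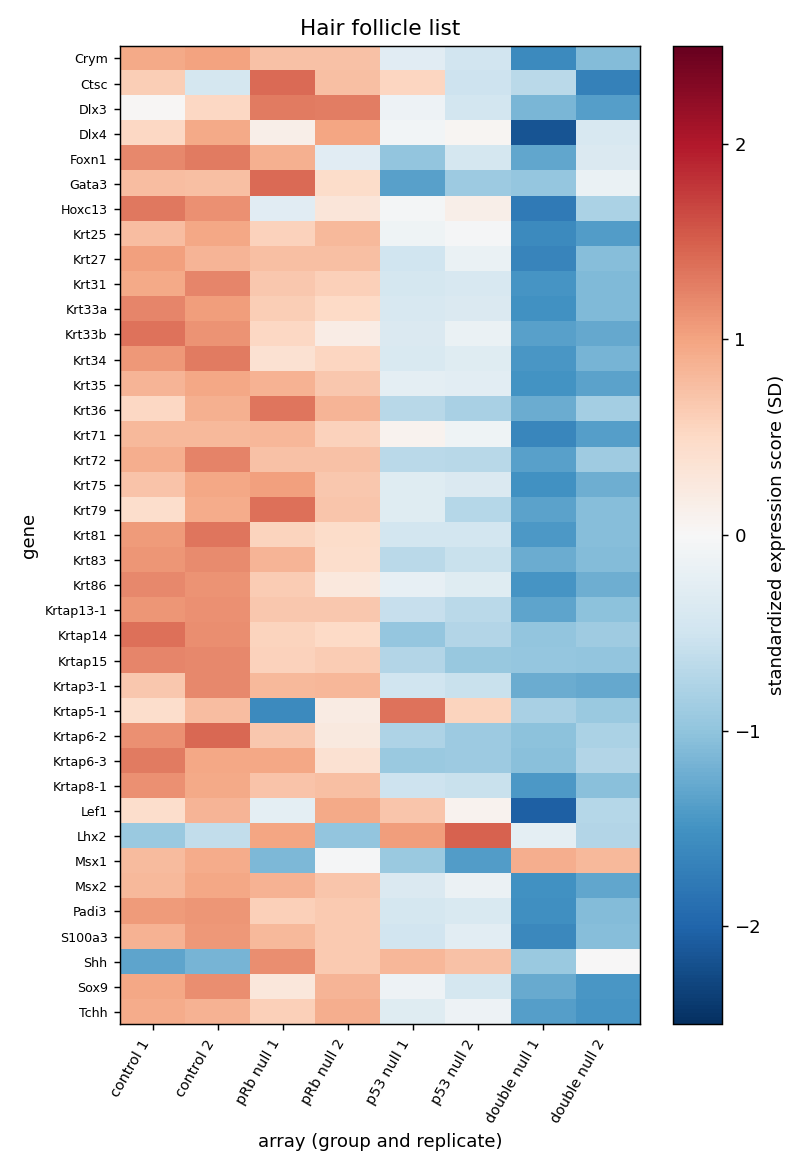
Standardized expression scores (colour, in SD of each gene over the 8 arrays) of the 39 measured genes of the hair follicle list (rows) in each array (columns, by group and replicate). Most rows are high in control and pRb_null and lowest in double_null, and 22 of the 39 genes fell between control and double_null.

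The third comparison set skin that lacked both proteins against control. Of the 39 hair follicle genes, 22 fell over all genes, 31 adjusted over the list alone and 34 at an unadjusted p under 0.05, with a median of −2.28 and an adjusted p of 8.5e-16 (adjusted p = 0.21 with an estimated correlation). The shaft keratins Krt34 (−2.5 ± 0.14, adjusted p = 0.022) and Krt35 (−2.32 ± 0.10, adjusted p = 0.014) and the inner root sheath keratin Krt25 (−2.36 ± 0.13, adjusted p = 0.021) were among them. Markers of macrophages and myeloid cells were higher, with a median of 1.496 over 23 members, 6 adjusted over the list alone, and an adjusted p of 5.4e-05 (adjusted p = 0.21 with an estimated correlation). Lysozyme Lyz2 differed by 2.32 ± 0.35 (adjusted p = 0.094) and the complement gene C1qb by 2.05 ± 0.31 (adjusted p = 0.094). Interferon response genes had a median of 1.06 over 35 members, 2 of them higher adjusted over the list alone, and an adjusted p of 0.00020 (adjusted p = 0.21 with an estimated correlation).

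Epidermal genes linked to stress and hyperproliferation were higher as a list in double_null, with a median of 1.54 over 29 members and an adjusted p of 0.0014 (adjusted p = 0.21 with an estimated correlation). Of these, 3 rose over all genes: the alarmin S100a8 (2.23 ± 0.08, adjusted p = 0.013), the wound-induced keratin Krt16 (2.28 ± 0.14, adjusted p = 0.026) and the epithelial cytokine Il1f9 (2.56 ± 0.16, adjusted p = 0.026). The connexin Gjb2 fell by 2.37 ± 0.20 (adjusted p = 0.036). The cornified envelope list was higher, with a median of 0.66 and an adjusted p of 0.034 (adjusted p = 0.21 with an estimated correlation), and basal keratinocyte genes were lower, with a median of −1.17, 6 of 23 lower adjusted over the list alone, and an adjusted p of 0.022 (adjusted p = 0.51 with an estimated correlation). Krt5, the keratin of the basal layer, differed by −2.26 ± 0.43 (adjusted p = 0.13). Adipocyte markers (median 1.01, adjusted p = 0.0083) and mast cell markers (median 1.21, adjusted p = 0.014) were higher, and the ribosomal protein list (median −1.08) and the list of Wnt, Hedgehog and Notch genes (median −1.12) were lower, each with an adjusted p of 0.015. With an estimated correlation the adjusted p was 0.26 for adipocyte markers and 0.21 for the other 3 lists. The E2F list (median 0.28) and the mitosis list (median 0.05) did not pass, with an adjusted p of 0.18 and 0.49. The E2F median ran from −0.241 to 0.863 with 1 array left out at a time. Its mean score was −0.741 and −0.054 in the control arrays, so whether E2F genes differ here is not settled.

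A total of 125 genes changed between double_null and control, 46 up and 79 down. The 10 that rose most were Ucp3, Il1f9, Esyt3, Ier3, Chrnd, Cd74, Hcar2, Dusp1, Etfdh and AY036118, by 2.42 to 2.59. Cd74, the invariant chain of antigen presentation, rose by 2.43 ± 0.09 (adjusted p = 0.012), and Dusp1 and Ier3 are immediate early genes. The 10 that fell most were Wrap73, Rpl37a, Zcchc9, Krtap5-2, Fbn2, Krt33b, Nectin2, Polr2a, Krt86 and Pdcd7, with differences from −2.61 to −2.51. Other probe sets of Rpl37a (−0.68 and −1.91), Nectin2 (−0.94) and Polr2a (−1.10) had the same sign without an unadjusted p under 0.05. The other probe set of Ucp3 was at 2.08 and passed that bound. Without 1 array at a time, the count of changed genes was between 4 and 10, and quantile normalization gave 4. Of the 46 control probe sets, 16 were higher and 2 lower at an unadjusted p under 0.05, with a median of 1.26. In the same arrays Xist, the RNA of the inactive X chromosome, scored −1.57 and −1.50 in double_null, −1.75 ± 0.31 from control (adjusted p = 0.12), which leaves the sex of the pooled animals open as a difference between the groups. Without double_null replicate 1, the adipocyte (adjusted p = 0.15), mast cell and Wnt lists (adjusted p = 0.054 each) lost their calls. The basal list lost its call without control replicate 2 or double_null replicate 2. The ribosomal list did so without control replicate 1 or double_null replicate 1, and the cornified list without control replicate 2 or double_null replicate 1. Their medians moved as well: the basal list was at −0.57 without control replicate 2, the cornified list at 1.40 without control replicate 1, and the ribosomal list at −0.65 and −0.70 without control replicate 1 and double_null replicate 1.

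Loss of p53 where pRb was already absent was tested by setting double_null against pRb_null. Hair follicle genes fell there too, with 18 of 39 past the threshold over all genes, 33 adjusted over the list alone, a median of −1.86 and an adjusted p of 5.0e-11 (adjusted p = 0.34 with an estimated correlation). Macrophage markers had a median of 1.55 and an adjusted p of 6.3e-06 (adjusted p = 0.16 with an estimated correlation). The mitosis list was lower, with a median of −0.94 and an adjusted p of 0.019 (adjusted p = 0.34 with an estimated correlation). Lower with the same adjusted p of 0.019 were skeletal muscle markers (median −1.305, 9 members lower and 2 higher adjusted over the list alone), melanocyte markers (−1.46) and basal keratinocyte genes (−1.11), and higher were the epidermal stress (1.07) and interferon lists (0.66). Mast cell markers were higher (1.08) and Wnt, Hedgehog and Notch genes lower (−0.90), each with an adjusted p of 0.029. With an estimated correlation these 7 lists had an adjusted p from 0.34 to 0.41. In all, 97 genes changed, 33 up and 64 down. That count was 0 to 5 with any array left out, and quantile normalization and a replicate block each gave 0. The receptor Sirpa, the matrix protein Tgfbi, Trbv1, Acad8 and Tfpi2 rose by 2.52 to 2.59, and Sf3a2, Golga4, Crim1, the retinoic acid receptor Rarg and Wdr12 fell, with differences from −2.61 to −2.55. Other probe sets of Acad8 (−1.42), Sf3a2 (0.98) and Crim1 (0.48) had the opposite sign. Fits without a control or p53_null array leave these differences unchanged, so only the arrays compared test the lists. The mitosis, muscle, basal and interferon lists lost their call without pRb_null replicate 2 and without double_null replicate 2. The melanocyte list lost it without pRb_null replicate 2 and without double_null replicate 1. The mast cell list lost it without pRb_null replicate 2 or either double_null array, and the stress list without pRb_null replicate 1 or either double_null array. The Wnt list lost its call without any 1 of the arrays compared, with medians from −1.18 to −0.631. The interferon median was 1.01 and 1.03 without pRb_null replicate 1 and double_null replicate 1, and 0.30 without double_null replicate 2. Of the 46 control probe sets, 0 were higher and 7 lower at an unadjusted p under 0.05, with a median of −0.66.

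Loss of pRb where p53 was already absent was tested by setting double_null against p53_null. Adipocyte markers were higher, 15 of 17 adjusted over the list alone, with a median of 2.12 and an adjusted p of 6.4e-09 (adjusted p = 0.082 with an estimated correlation). The interferon list (median 1.44) and the epidermal stress list (median 1.498) were higher, with an adjusted p of 2.0e-07 and 5.3e-07. The mitosis list was lower, with a median of −1.08, 0 members higher and 18 lower at an unadjusted p under 0.05, and an adjusted p of 9.5e-07. For these 3 lists the result was adjusted p = 0.082 with an estimated correlation. The proliferation marker Mki67 differed by −1.54 ± 0.25 (adjusted p = 0.18) and Plk1, a mitotic kinase, by −1.56 ± 0.31 (adjusted p = 0.22). Acute stress and handling genes were higher, with a median of 1.59 and an adjusted p of 0.00031 (adjusted p = 0.16 with an estimated correlation). The hair follicle list was lower here too, with a median of −0.96, 24 of 39 lower and 1 higher adjusted over the list alone, and an adjusted p of 5.5e-05 (adjusted p = 0.35 with an estimated correlation); it passed with any array left out. Macrophage markers were higher, with a median of 1.11 and an adjusted p of 0.0011 (adjusted p = 0.082 with an estimated correlation), but at 0.56 without double_null replicate 1 they lost their call (adjusted p = 0.072). Wnt, Hedgehog and Notch genes (median −1.09, adjusted p = 3.7e-05), basal keratinocyte genes (−0.81, adjusted p = 0.0037) and ribosomal proteins (−0.83, adjusted p = 0.012) were lower. So was the list of cell cycle inhibitors and pRb pathway genes (−0.86, adjusted p = 0.014), which also names cyclins, their kinases and E2F factors. With an estimated correlation these 4 lists had an adjusted p from 0.082 to 0.35. Of these 4, the Wnt list passed with any array left out (at −0.72 without double_null replicate 1). The basal list was at −0.53 without p53_null replicate 2, and it lost its call without double_null replicate 2 (median −0.37). The list of cell cycle inhibitors and pRb pathway genes lost its call without double_null replicate 2 (median −0.52) and without p53_null replicate 1 (−0.723). The ribosomal list lost its call without p53_null replicate 2 (median −0.65) and without double_null replicate 1 (−0.565). In all, 5 genes changed, and 0 or 1 without 1 array at a time: Slurp1 (2.52 ± 0.07) and Bbox1 (2.35 ± 0.10) rose, and Tnmd (−2.08 ± 0.08), Rxylt1 (−1.81 ± 0.07) and Tnnc1 (−1.77 ± 0.05) fell. The Y-linked genes Uty, Kdm5d and Eif2s3y differed between the same groups by 2.27, 2.33 and 2.17, and the 46 control probe sets had a median of −0.15, with 5 higher and 1 lower at an unadjusted p under 0.05.

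Whether the losses add up was tested by their interaction, the effect of pRb loss without p53 minus its effect with p53. The mitosis list was lower in double_null than the separate effects add up to, with a median of −1.62, 16 of 58 members lower and 0 higher at an unadjusted p under 0.05, and an adjusted p of 1.5e-07 (adjusted p = 0.16 with an estimated correlation). The E2F list had a median of −1.17 (adjusted p = 0.00030, and adjusted p = 0.29 with an estimated correlation). In the other direction, the epidermal stress list had a median of 1.30 (adjusted p = 0.0030, and adjusted p = 0.24 with an estimated correlation). The hair follicle list had a median of −0.53 and did not pass (adjusted p = 0.064). No single gene passed: limma's unmoderated test gave 0 genes and its moderated test 0, with 1214 and 1102 at an unadjusted p under 0.05. The smallest p belonged to Slurp1 (2.61 ± 0.10), Fscn1 (−3.09 ± 0.13), Ptprf (−2.72 ± 0.12), Bbox1 (2.85 ± 0.14) and Agpat5 (3.25 ± 0.17), each with an adjusted p of 0.085. Xist also had an interaction, of −2.65 ± 0.44 (adjusted p = 0.31), and the interaction uses the control arrays, which stand apart in the control probe sets. Of these 46, 1 had a positive and 12 a negative interaction at an unadjusted p under 0.05, with a median of −1.48.

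**Figure D3:**
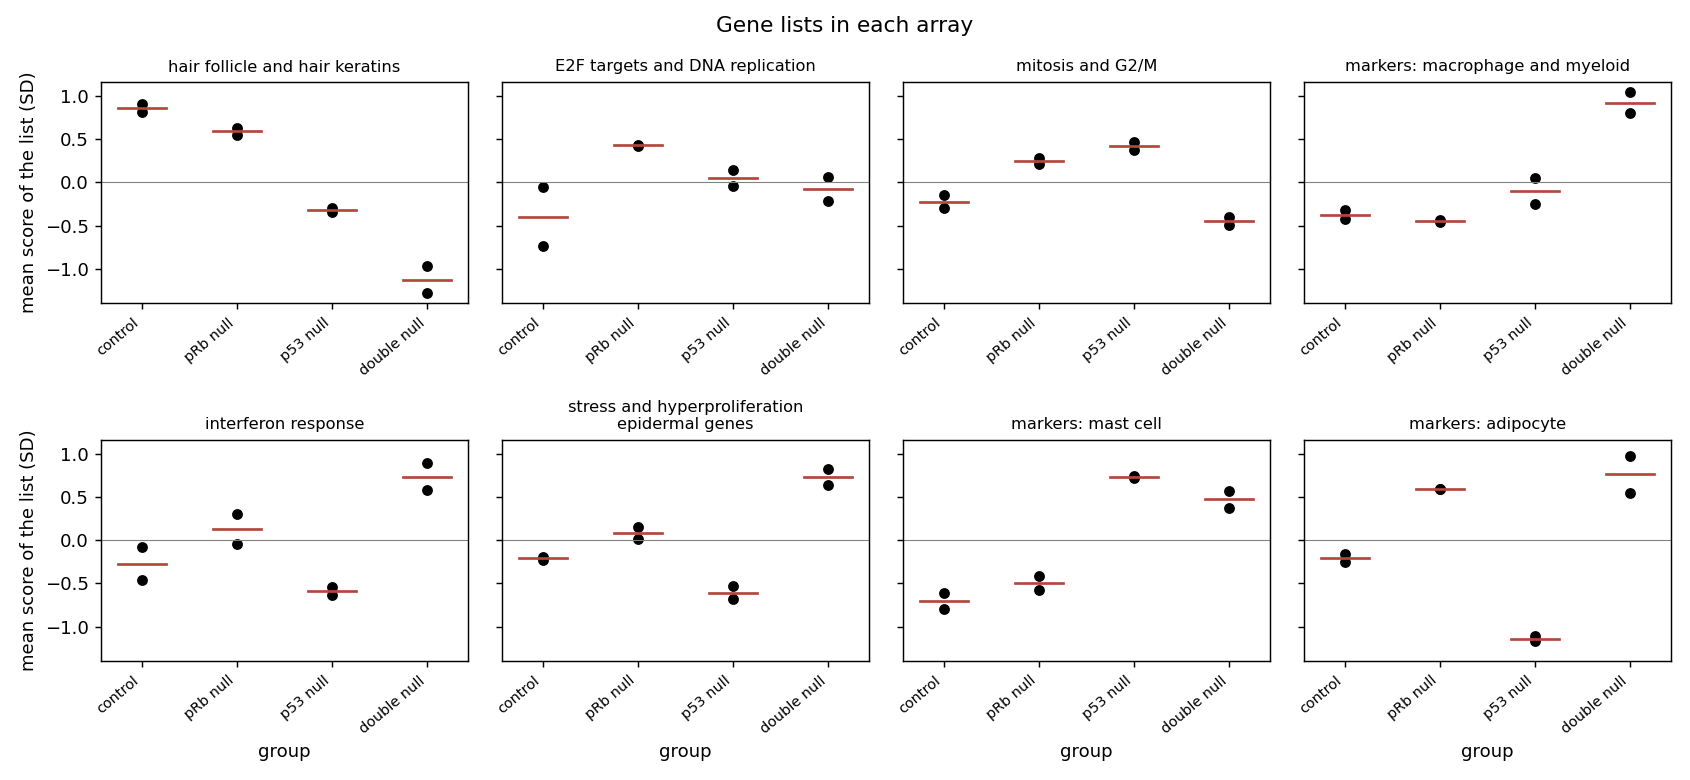
Mean standardized score of 8 gene lists (vertical axis, in SD of each gene over the 8 arrays) in each array, by group (horizontal axis). Points are single arrays and the line is the mean of 2. The hair follicle list is above 0 in control and pRb_null and below 0 in p53_null and double_null, and the mitosis list is between −0.494 and −0.398 in double_null.

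Averaged over pRb status, loss of p53 changed 195 genes, 74 up and 121 down, in 4 arrays against 4. Hair follicle genes fell, 28 of 39 over all genes and 32 adjusted over the list alone, with a median of −1.68 and an adjusted p of 5.95e-13 (adjusted p = 0.39 with an estimated correlation). Of 10 mast cell markers, 4 rose over all genes: Cma1, Tpsab1, Cpa3 and Hdc, by 1.55 to 1.83. The list had an adjusted p of 0.00027 (adjusted p = 0.31 with an estimated correlation). Macrophage markers had a median of 0.87 (adjusted p = 0.00027, and adjusted p = 0.29 with an estimated correlation), and the haemoglobin scavenger receptor Cd163 rose by 1.83 ± 0.14 (adjusted p = 0.029). The macrophage list was high mostly in double_null. Its mean score was 1.039 and 0.795 there, −0.246 and 0.051 in p53_null and −0.429 and −0.318 in control. It did not pass in p53_null against control, so the average does not show an effect of p53 loss alone. Basal keratinocyte genes as a list did not pass (adjusted p = 0.21), although Egfr (−1.73 ± 0.16), Cdh3 (−1.57 ± 0.15) and Lgals7 (−1.76 ± 0.19) fell. The genes with the largest differences were Asph, 2610524H06Rik, Srgn, Cd163 and Hdc, which rose by 1.83 to 1.85, and Atf7ip2, Lsm12, Hacd2, Map3k5 and Plxna2, which fell, with differences from −1.83 to −1.82. Of the other probe sets of Asph, 3 had the opposite sign (−1.17, −0.72 and −0.53) and 1 agreed (0.75). Without 1 array at a time, the count was between 4 and 15, and quantile normalization gave 0. Of the 46 control probe sets, 10 were higher and 4 lower with p53 loss at an unadjusted p under 0.05, with a median of 0.32.

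Averaged over p53 status, loss of pRb changed 6 genes, 1 up and 5 down (0 to 2 without 1 array at a time), among them Tnnc1 (−1.60 ± 0.04), Zcchc9 (−1.46 ± 0.06) and Tnmd (−1.31 ± 0.06), a gene of tendon. Adipocyte markers were higher, 15 of 17 adjusted over the list alone, with a median of 1.56 and an adjusted p of 7.7e-09 (adjusted p = 0.19 with an estimated correlation). The interferon list (median 0.95, adjusted p = 4.0e-06) and the epidermal stress list (median 0.88, adjusted p = 4.6e-05) were higher, with adjusted p = 0.20 and adjusted p = 0.19 with an estimated correlation. Both passed in double_null against p53_null (medians 1.445 and 1.498) but not in pRb_null against control, so the averages do not show an effect of pRb loss alone. Acute stress and handling genes were higher too (median 0.98, adjusted p = 0.0029 in the list test), so a handling response was not separated from these lists. Markers of Langerhans, dendritic and T cells were also higher (0.85, adjusted p = 0.034). Neither passed with an estimated correlation. The hair follicle list was lower, with a median of −0.59 and an adjusted p of 0.00015 (adjusted p = 0.41 with an estimated correlation). It too passed in double_null against p53_null but not in pRb_null against control, so its average does not show an effect of pRb loss alone. Of the 46 control probe sets, 13 were higher and 0 lower with pRb loss at an unadjusted p under 0.05, with a median of 0.66.

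The 3 comparisons against control share the control arrays, so their differences correlate with no effect at all. Across genes, which are not independent replicates, the correlation of p53_null and double_null was 0.558, where unchanged groups gave 0.5 in simulation, and the covariance was 0.772 against a simulated 0.365. The correlation of pRb_null with p53_null was 0.346 and with double_null 0.391. Of the 13 genes that fell in p53_null, 10 also fell in double_null, where independent lists would share 0.1. That value leaves out the shared control arrays. At an unadjusted p under 0.05, 54.3% of the 900 genes lower in p53_null were also lower in double_null, where unchanged groups with shared controls gave 30.9% in simulation. The control arrays also differed in the control probe sets, so no shared effect of the genotypes can be read from the overlap.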

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

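All tests of explanations in this part were chosen after the results they bear on had been seen.

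The interaction of pRb and p53 loss passed the list test for 12 lists, each a difference between the effect of pRb loss with and without p53. The median interactions were −1.625 for mitosis, −1.135 for skeletal muscle markers, −1.167 for E2F targets and 1.303 for epidermal stress genes. They were −1.819 for melanocyte markers, 1.299 for macrophage markers, −0.794 for Wnt, Hedgehog and Notch genes and 1.237 for interferon response. They stood at 1.122 for adipocyte markers, −0.824 for basal keratinocyte genes and 1.314 for acute stress genes. The list of cell cycle inhibitors and pRb pathway genes was at −1.212. It is named cell cycle inhibitors below, although it also holds cyclins, their kinases and E2F factors. With an estimated correlation 0 of the 12 passed. With 1 array left out at a time, the lists that lost their call in some fit had a highest adjusted p of 0.11 for interferon response (without control replicate 1), 0.10 for macrophage markers, 0.17 for adipocyte markers and 0.23 for acute stress genes (each without double_null replicate 1), and 0.21 for basal keratinocyte genes and 0.22 for cell cycle inhibitors (both without double_null replicate 2). Medians also moved by over 1.5 times: interferon response to 0.805 and 0.796 without control replicate 1 and pRb_null replicate 2, macrophage markers to 0.722 without double_null replicate 1, Wnt, Hedgehog and Notch genes to −0.429 and −0.304 without pRb_null replicate 1 and double_null replicate 1, basal keratinocyte genes to −1.51, −1.242 and −0.23 without control replicate 2, pRb_null replicate 2 and double_null replicate 2, and cell cycle inhibitors to −0.71 and −0.65 without control replicate 2 and double_null replicate 2.

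The hybridization control probe sets, which the comparisons do not use, had a mean score of 1.825 in p53_null replicate 2, against 0.932 in the higher control array. The Gapdh control probe sets were higher in each mutant array than in both control arrays: the lowest mutant array scored −0.302, 0.072 and 0.353 at the 3' end, the middle and the 5' end. In all, both control arrays lay below every mutant array for 10 of 19 mouse control probe sets and for 10 of 27 bacterial ones, among them 5 of 5 and 7 of 9 at the 5' end. The reverse held for 1 and 1, and chance gives 3.6% each way. A difference in RNA quality or in the handling of both control arrays was not separated from genotype by the design. For its test below, the bounds were set when the values were known in part.

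The hair follicle list was lower in both genotypes without p53. Against a single array as the cause, the median for p53 loss stayed at −1.606 or lower whichever array was left out. Against the sex of the animals as the whole cause, Uty, Eif2s3y and Kdm5d differed between double_null and p53_null by a median of 2.273 while the hair list was lower than control in both. A lower share of epithelium as the only change would raise all other cell types alike. In p53_null adipocyte markers were lower (−1.145) while mast cell markers were higher, which argues against it as the only change there. Other cell types may change on their own, so a lower share as a part stays open. In double_null the lowest such list was at −0.569 without passing. That leaves out the lists of melanocytes (−1.09, adjusted p = 0.081) and sebaceous gland, whose cells sit in or on the follicle. By these lists a lower share of epithelium cannot be told apart in double_null, because no other cell type list passed in the lower direction. Epidermal lists went both ways there against control. Basal keratinocyte genes were lower (−1.172). Epidermal stress genes were at 1.451 or higher with any array left out, and the cornified envelope list was at 0.655. With an estimated correlation none passed. A lower share as the only change would lower all epidermal lists, so the higher ones argue against it there. As a part it stays open. Against a technical difference of both control arrays as the whole cause, the list was lower also when pRb_null took the place of control, at −1.04 in p53_null and −1.86 in double_null. The 46 mouse and bacterial control probe sets also differed between double_null and pRb_null, with a median of −0.655, so a difference in RNA quality between other groups stays open, as does a part in the size of the difference from control. Between double_null and p53_null, which both lack p53, the list was lower as well, at −0.958. The Y-linked genes differ between these same groups, so the sex of the animals stays open as a part of the pattern. The age of the pups at sampling and an effect of genotype also stay open.

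The mitosis list was lower in double_null than the separate losses add up to. The median interaction stayed at −1.416 or lower whichever array was left out, and was −1.562 with each array's median set to 0, which argues against a single array and an offset of whole arrays. The sex of the pooled animals cannot be told apart from this pattern, because Xist itself had an interaction of −2.655. A technical difference of both control arrays cannot be told apart from it either, because the interaction uses them and the 46 mouse and bacterial control probe sets had a median interaction of −1.484; without the control arrays the list was at −0.94 or lower in double_null against each single loss. An effect of genotype stays open, as a hypothesis.

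Myeloid, interferon and epidermal stress lists were higher in double_null than in control. The lowest of the 3 medians was 0.769 with any array left out, which argues against a single array. A handling response of the tissue cannot be told apart, because the acute stress list had a median of 0.203 against control and did not pass with all arrays, but ran from 0.011 (without control replicate 1) to 0.722 (without control replicate 2) and passed without double_null replicate 2 (0.652, adjusted p = 0.044); against p53_null it was at 1.592 and passed with any array left out. A technical difference of both control arrays as the whole cause forbids double_null from differing from the single losses. Against the mean of both single losses, a difference that leaves out the control arrays, the 3 lists passed with all arrays and with any array left out, the lowest median being 0.912 (macrophage markers without double_null replicate 1); with an estimated correlation none passed. This is the third form of the test, set after values against each single loss were known. Its outcome follows largely from those values, so it adds no support of its own. The second took for each list the single loss against which it passed, which could hardly fail, and was dropped. The first bound, that all 3 pass against pRb_null in every such fit, was not met. The interferon list was at 0.662 there and at 0.302 without double_null replicate 2. The stress list lost its call without pRb_null replicate 1 or either double_null array. Against p53_null macrophage markers lost their call without double_null replicate 1 (0.561, adjusted p = 0.072). The values against the single losses thus argue against the control arrays only as the whole cause. For the interferon and stress lists they do so more through p53_null (1.445 and 1.498) than through pRb_null (0.662 and 1.069). A part in the size of the difference from control stays open. Against the mean of both single losses the acute stress list was higher too (median 0.708, adjusted p = 0.016 in the list test, 0.29 with an estimated correlation). A handling response therefore stays open in that test as well. The 46 mouse and bacterial control probe sets differed between double_null and pRb_null, with a median of −0.655, so a difference in RNA quality between these groups stays open too. The sex of the pooled animals and an effect of genotype stay open, untested for this pattern.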

How the results depend on the processing

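Counts of changed genes depended on the processing in every comparison but the interaction. There each processing run gave 0, and leaving out either control or either double_null array changed the count. With quantile normalization each called gene kept its sign and an unadjusted p under 0.05. With the mean of a gene's probe sets, 124 of the 125 genes called in double_null against control kept their sign, and 193 of the 195 called for p53 loss averaged. The replicate block and array weights could not change a sign. Each group holds 1 array of each number, and the 2 arrays of a group had equal weights, so the differences stayed the same. In both settings each called gene kept an unadjusted p under 0.05. Counts follow in the order pRb_null, p53_null and double_null against control, double_null against pRb_null, double_null against p53_null, interaction, pRb loss averaged and p53 loss averaged, for which the main counts were 3, 17, 125, 97, 5, 0, 6 and 195. Quantile normalization gave 0, 0, 4, 0, 0, 0, 0 and 0. Every probe set gave 0, 27, 192, 92, 8, 0, 1 and 285. The mean of a gene's probe sets gave 0, 15, 118, 72, 17, 0, 12 and 194. Array weights gave 0, 32, 115, 27, 32, 0, 1 and 162. Only the 2 groups compared, with 2 residual degrees of freedom, gave 0 in each of the first 5. For the averaged effects of pRb and p53 loss, 2 groups of 4 arrays gave 0 and 56, and the additive model 2 and 153. The planned moderated test, made an alternative after seeing the data, gave 0 throughout. Array medians set to 0, chosen after seeing the data, gave 0, 3, 154, 101, 2, 0, 5 and 160. Without 1 array at a time the ranges were 0 to 1, 0 to 7, 4 to 10, 0 to 5, 0 to 1, 0 to 1, 0 to 2 and 4 to 15, with 3 residual degrees of freedom and the lone array assumed to vary like the other groups. The order of the genotypes by count depended on the arrays: without control replicate 1, p53_null gave 7 and double_null 6, and without either pRb_null array both gave 5. The cause of the other changes was not tested.

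The replicate block gave 0, 0, 5, 0, 0, 0, 0 and 2. Whether the replicate numbers pair the arrays is not given in the sources used here. Correlations of same-numbered deviations ran from −0.163 to 0.197. The mean hybridization control score lay between −0.821 and −0.26 in the replicate 1 arrays. In replicate 2 it was 0.932 in control, 1.825 in p53_null and 0.439 in double_null, but −0.863 in pRb_null. A batch that runs with the number in part of the groups therefore stays open. With the pRb_null numbers crossed, chosen after seeing the data, double_null gave 17 against control and 3 against pRb_null, p53 loss averaged gave 30, and the others with main calls gave 0, so the block counts depend on the numbering.

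Lists past the threshold numbered 3, 5, 10, 10, 14, 12, 8 and 3. With an estimated correlation there were 0 in each. Fry gave 0, 4, 11, 11, 14, 6, 9 and 5, the replicate block 3, 5, 10, 10, 14, 12, 8 and 3, and the ordinary statistic, added after seeing the data, 7, 8, 12, 9, 16, 13, 14 and 4. Without 1 array at a time the ranges were 1 to 3, 3 to 7, 5 to 12, 3 to 10, 12 to 14, 9 to 12, 7 to 14 and 3 to 5.

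Over 4958 genes with several probe sets, the median r of the probe set used with the others was 0.212. In 44.1% of these genes it had a negative r with at least 1 other probe set. A list value therefore rests on probe sets that often disagree. Of 38 other probe sets of named genes, 9 had the opposite sign: Ptprf (−0.532 for pRb_null and −1.053 for p53_null), Fscn1 (−0.577), Acad8 (−1.425), Sf3a2 (0.981), Crim1 (0.48) and Asph (−1.166, −0.53 and −0.718). Ptprf (2.344 and 1.768), Fscn1 (1.566 and 1.656) and Asph (0.749) also had probe sets that agreed in sign. Of the 38, only 14 had the same sign and an unadjusted p under 0.05, and 15 had the same sign without it. Among those 15 were probe sets of Nectin2 (−0.944) and Polr2a (−1.103) for double_null, Fzd6 (−0.559) for p53_null, each against control, and Wdr12 (−0.615) for double_null against pRb_null. No other alternative reversed a named gene, but most of the alternatives could not. The moderated test, the replicate blocks, array weights, the additive model and the fits on fewer or merged groups leave the difference unchanged. Leaving out an array cannot flip a sign where the groups do not overlap, and most named genes were chosen by that rule. Quantile normalization, array medians set to 0 and the mean of a gene's probe sets were free to reverse a sign and did not. The filter on dim genes, for genes and for lists, the moderated test with trend and robust estimation and the 2-fold threshold were not run, because scores hold no levels or folds. Signal over background is unknown for the same reason.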

Other observations

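The list tests in this part were planned; the gene test, the splits and the test of an explanation were chosen after seeing the data.

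Melanocyte markers were lower in double_null than in p53_null, with a median of −1.40 over 11 members and an adjusted p of 0.0018 (adjusted p = 0.14 with an estimated correlation). They were lower also against pRb_null (median −1.46, adjusted p = 0.019, and adjusted p = 0.34 with an estimated correlation). There they lost their call without pRb_null replicate 2 (median −1.384) and without double_null replicate 1 (median −1.722). Against control, Dct, an enzyme of melanin synthesis, fell by 2.02 ± 0.18 (adjusted p = 0.040), and the list did not pass (median −1.09, adjusted p = 0.081). FVB mice are albino, so these genes speak of pigment cells and not of coat colour. Between double_null and p53_null the lists of Langerhans, dendritic and T cells (median 1.06, adjusted p = 0.0086) and oxidative phosphorylation (median 0.85, adjusted p = 0.025) were higher, with adjusted p = 0.14 and adjusted p = 0.33 with an estimated correlation. The latter list lost its call without double_null replicate 1 (median 0.722) and without p53_null replicate 1 (median 0.658). Without double_null replicate 2 the median of the former was 0.51.

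The number of genes called for p53 loss was compared with other ways of splitting the 8 arrays into 4 and 4. The real split gave 56 genes, the highest of the others 0, and 1 of the 35 splits, the smallest share possible, gave as many. This excludes chance only if the 8 arrays are independent, which the sources used here do not say. If the 2 arrays of a genotype came from 1 pool, only 3 splits keep the genotypes whole, too few for a share under 0.05. For pRb loss no gene was called in such a fit; at an unadjusted p under 0.05 the real split gave 995 genes, 3 of the 35 splits gave as many, and the highest of the others, the split by p53 status, gave 2332, and another, which follows no genotype, gave 1223, so chance is not excluded.

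A later start of hair shaft formation may account for the lower hair follicle list. Early follicle genes (Shh, Lhx2, Sox9, Lef1, Wnt10b, Gli1, Ptch1 and Edar) would then be kept while shaft genes are low. Their median difference for p53 loss was 0.473, but 3 of the 8 were below 0 and Sox9 differed by −1.64 ± 0.17, so the test does not decide. In double_null, where the hair list was lowest, their median against control was −0.2, with 4 of 8 below 0, Sox9 at −2.43 and Lef1 at −2.02, against a median of 0.78 in p53_null. The first form of the test had a ninth gene, Bmp2, with which the median was 0.614, and no condition that single genes be kept. Bmp2 was taken out and that condition was added after the value had been seen; without the condition the test would have favoured the explanation with either set of genes. Values of Shh, Lef1 and Ptch1 had been seen before the genes were chosen, and 4 of the 8 are members of the hair follicle list.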
